A study of Mus musculus with 8 samples.

How the data were processed

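Total RNA of 8 cultures of AML12 mouse hepatocytes, 4 wild-type and 4 with the VWA8 gene deleted, was purified with DNase treatment, labelled with biotin and hybridised to an Affymetrix mouse array, per the labels' protocols. The values analysed are those the authors deposited, 1 value per probe set and array on a log2 scale, running from 0.44 to 13.55. The log2 scale was read from the deposited values. The background correction, normalization and summarisation behind them are not given in the sources used here. Because the medians of the 8 arrays lay within 4.27 and 4.33, no further normalization was added. No separate measure of background was used, so a dim signal cannot be told from no expression, and large folds from a dim baseline are compressed.

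Genes were named from the platform's annotation. Of 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none listed. Control probe sets are not marked in the files used here, so none was left out. For gene-level results each of the 22180 genes with a single-symbol probe set was represented by the probe set with the highest mean over all 8 arrays. Of 1082 genes with more than 1 probe set, 262 had a probe set that passed the threshold, and in 2 of them probe sets passed in opposite directions. Chromosomes and the order of genes came from a gene table of assembly GRCm38.p6, which 21994 genes matched by Entrez Gene identifier.

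Genotypes were compared with linear models and empirical Bayes moderation in limma 3.58.1 (R 4.3.3), genotype as the only term and all 8 arrays in the fit. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all probe sets or all genes, with a threshold of 0.05. The design text describes separate cultures, and nothing more is known of their independence. For Vwa8 the 70 arrangements of the arrays were also enumerated in an exact permutation test.

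Before the data were examined, 53 gene lists were fixed, with 1716 symbols of which 1550 were measured, 16 of these under an older name. Each list was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 53 lists, then with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. In the 30 lists that passed, the median and the test had the same sign. Counts of members that changed use the adjustment over all genes unless said otherwise. Chromosomes were tested as gene lists with an estimated correlation. Genes were named by a rule fixed beforehand. It takes Vwa8, the 8 largest rises and the 8 largest falls among genes past the threshold whose groups did not overlap and whose brighter group exceeded the median probe set, up to 4 members with the smallest adjusted p of each list described, and Hnf4a, Alb, Afp, Ttr, Apoa1, Cat, Sod2, Hmox1, Nqo1, Ppargc1a, Cpt1a and Mki67 whatever their values. The rule was applied in full to the 19 lists that passed with both correlations.

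Alternatives fixed beforehand were the replicate number as a block, quantile normalization, median centring, an intensity trend with robust variances, array weights, leaving out the dimmest 25% or 50% of probe sets, the mean of a gene's probe sets, and leaving out each array. A further one, chosen after seeing the data, subtracted from the knockout values the median log2 fold change of the 30 nearest brighter genes on each side along the chromosome. A planned change of the offset did not apply to log2 values, and a planned exclusion of probe sets by identifier suffix did not apply because no identifier carried those suffixes.

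The fit was tested on simulated data drawn from the real means and spreads of the 22180 genes, with 200 genes changed between 4 and 4 arrays. It recovered 52.2% of genes changed by 0.5, 82.1% of those changed by 1 and 100% of those changed by 2 on the log2 scale, each in the right direction, and 7 of its 163 calls were false. The simulated noise was independent between genes, and far fewer genes were changed than the 4626 that passed in the data. These rates therefore check the fit and do not describe the real comparison. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.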

Results

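AML12 is a line of hepatocytes from a mouse liver, and VWA8 is a mitochondrial protein with an ATPase domain. In this study the VWA8 gene was deleted from these cells by CRISPR/Cas9, and separate cultures of wild-type and knockout cells were compared after differentiation, to find which transcripts change with the loss of the gene. Total RNA of 4 wild-type and 4 knockout cultures was hybridised to an Affymetrix mouse expression array, 1 array per culture. The medium of both groups contained insulin and dexamethasone, a synthetic glucocorticoid. Array medians lay between 4.27 and 4.33 on the log2 scale. Values correlated with r between 0.985 and 0.989 among the 6 pairs of wild-type arrays, between 0.986 and 0.989 among the 6 pairs of knockout arrays, and between 0.978 and 0.984 among the 16 pairs across genotypes. The first principal component held 33.3% of the variance and separated the 2 genotypes, and the second, with 14.5%, set wild-type replicate 3 furthest from the others. Replicate 3 was also the lowest of the knockout arrays on the second component. The precision of every value is limited by the 4 arrays per group. How many knockout clones were used is not given in the sources used here, so a difference between clones and an effect of the deletion cannot be separated.

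The Vwa8 transcript itself was far lower in the knockout. Its probe set, 17302161 (Entrez Gene 219189, on chromosome 14 in assembly GRCm38.p6), gave 8.95 ± 0.041 in wild-type cells (mean ± SD, n = 4) and 5.18 ± 0.116 in knockout cells (n = 4), a 13.6-fold decrease. The single wild-type arrays read from 8.91 to 9.01 and the knockout arrays from 5.07 to 5.33. The log2 fold change was -3.77 ± 0.070 (SE), and the exact permutation test of the 2 groups gave p = 0.0286, two-sided, the smallest p that 4 against 4 arrays allow. Where the probes lie relative to the deleted part is not given in the sources used here, so the remaining signal shows neither absence nor presence of a functional transcript. Of the 5 nearest measured genes on each side, 2 rose (Mtrf1, by 0.54 ± 0.064, and Kbtbd7, by 0.25 ± 0.061) and 1 fell (Dgkh, at -0.50 ± 0.118), and the median over the 10 was -0.02. These neighbours were named after their values were seen.

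The knockout cells expressed more of the genes of differentiated hepatocyte function and less of the genes of cell division and of the targets of TGF-beta and YAP. Rises were led by Iqgap2, a scaffold protein, at 15.4-fold, and Slc10a1, the bile acid uptake transporter of hepatocytes, at 10.6-fold. Among the largest falls were Vwa8 itself and Serpinb9b, a serine protease inhibitor, at 15.1-fold or -3.92 ± 0.102, which shrank to -2.51 with the mean of its probe sets in place of the brightest one. Of 22180 genes, 4626 (20.9%) passed an adjusted p of 0.05 in limma, 2314 higher and 2312 lower in the knockout. A change of at least 2-fold was seen in 450 of them, 219 higher and 231 lower. Over all 41345 probe sets, 4585 passed, 2318 higher and 2267 lower, including 708 of the 16010 probe sets for which no gene was listed. The 4 arrays of one genotype all lay above the 4 of the other for 26.1% of genes, where chance alone gives 2.86%. The median log2 fold change over all genes was -0.003, and the median absolute change among the genes that passed was 0.41.

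Among the other largest rises, log2 fold changes (± SE, 4 arrays per group throughout) were 3.23 ± 0.107 for Hsd3b2, a steroid dehydrogenase, 2.90 ± 0.195 for Akr1c18, a hydroxysteroid dehydrogenase, and 2.82 ± 0.132 for Aadac, a microsomal esterase. Pax3, a transcription factor better known from neural crest and muscle, rose by 3.05 ± 0.097 from a wild-type mean of 4.71, near the array median. Nrn1, which encodes neuritin, rose by 2.78 ± 0.121. Among the other largest falls were Osmr, the receptor subunit for oncostatin M, at -2.72 ± 0.112, and Ccl2, a monocyte chemokine, at -2.60 ± 0.134. Cd109, a membrane protein that binds TGF-beta, stood at -2.44 ± 0.106 and Nts, which encodes neurotensin, at -2.43 ± 0.143. All of these passed the limma test with adjusted p no higher than 1.54e-05.

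**Figure D1:**
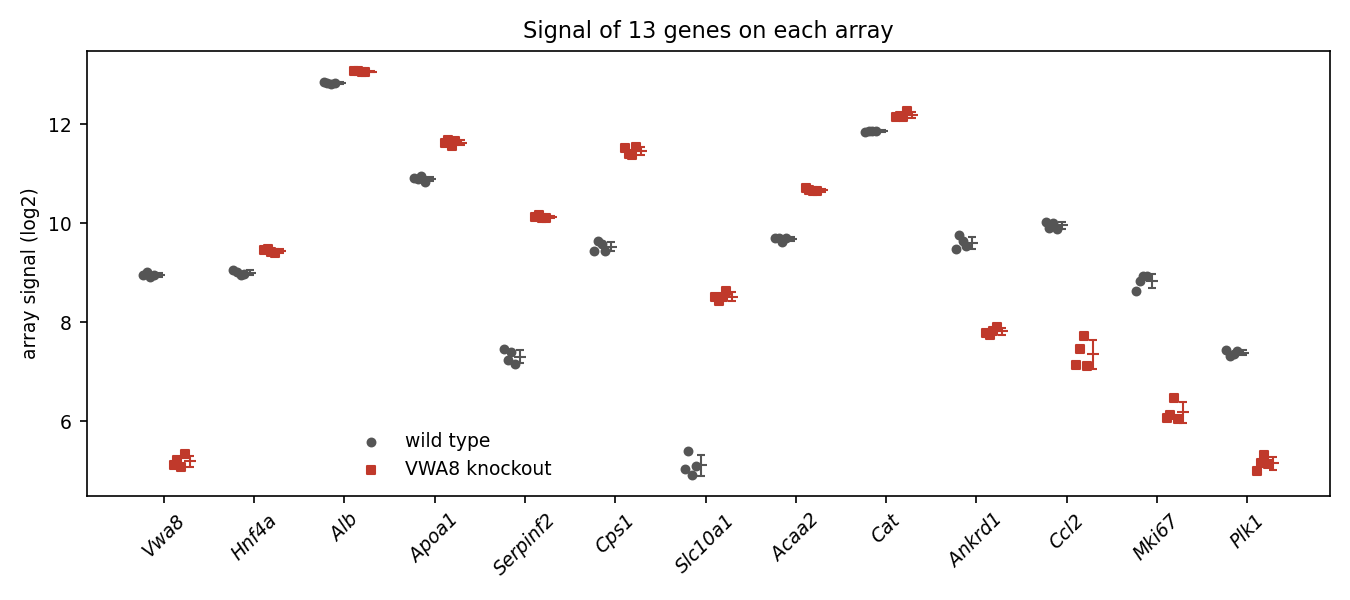
Signal of 13 genes on each array (log2, vertical axis) in wild-type cells (grey circles) and VWA8 knockout cells (red squares), 4 arrays each; the short bar with whiskers beside each set of points is the mean ± SD. The 4 knockout arrays lie apart from the 4 wild-type arrays for each of the 13 genes, below them for Vwa8, Ankrd1, Ccl2, Mki67 and Plk1 and above them for the other 8.

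Genes of plasma proteins that hepatocytes secrete rose almost as a whole. Of 45 measured members of this list, fixed before the data were examined, 42 rose and 1, Ambp, fell (the same counts when adjusted over the list alone), with a median log2 fold change of 0.92 and an adjusted p of 1.68e-31 in camera, limma's test of a gene list against all other genes. That p rests on the preset correlation of 0.01. With the correlation estimated for this list, 0.184, the camera adjusted p was 0.0118. Serpinf2, which encodes alpha-2-antiplasmin, rose by 2.82 ± 0.076, Serpinc1 (antithrombin) by 2.34 ± 0.079, Vtn (vitronectin) by 1.79 ± 0.062 and Hp (haptoglobin) by 1.78 ± 0.062. Apoa1, the main protein of high density lipoprotein, rose by 0.73 ± 0.056. Albumin and transthyretin, among the brightest signals on the array, moved less: Alb by 0.23 ± 0.048 from a wild-type mean of 12.84, and Ttr by 0.24 ± 0.054. Changes of signals so near the highest value on the arrays, 13.55, can be compressed. Subtracting the median change of neighbouring genes, an alternative added after the data were seen, left Alb at 0.39, and Ttr at 0.16 (adjusted p = 0.0747; 5.23e-06 to 0.0747 over all alternatives). Afp, the fetal counterpart of albumin, stood at -0.40 ± 0.130 and missed the threshold (adjusted p = 0.0600; 5 of 17 alternatives put it past, among them leaving out knockout replicate 1 at -0.50, with adjusted p from 0.0236 to 0.245). Over all alternatives the change of Afp ran from -0.50 to -0.24.

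HNF4A, a nuclear receptor that drives hepatocyte genes, and its targets were higher too. Hnf4a rose by 0.45 ± 0.055 (0.34 to 0.47 over all alternatives, past the threshold in each). It lies on chromosome 2, whose genes were shifted up as a group. Of 40 listed targets, 27 rose and 1, Ambp, fell (29 and 1 when adjusted over the list alone; median 0.70, camera adjusted p = 1.14e-14). Tat, the aminotransferase that starts tyrosine breakdown, rose by 2.51 ± 0.063. G6pc, the catalytic subunit of glucose-6-phosphatase, rose by 2.62 ± 0.092, and Apoh, a plasma glycoprotein, by 1.54 ± 0.070. The fixed lists share members, so their results are not independent of each other. Of the HNF4A targets, Tat is also on the glucocorticoid and amino acid lists, G6pc on the gluconeogenesis list and Slc10a1 on the bile acid list. The list of hepatocyte transcription factors had 10 of 23 members higher and 2, Foxa1 and Cebpb, lower (camera adjusted p = 0.00289), a call lost with an estimated correlation (adjusted p = 0.0830). Foxa1, Cebpb and Ambp were named after their values were seen, as is each single exception to a list named further on.

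Enzymes of amino acid breakdown and urea synthesis were higher. Of 56 such genes, 35 rose and 2, Got1 and Ftcd, fell (40 and 3 when adjusted over the list alone; median 0.44, camera adjusted p = 7.47e-19). Cps1, the entry enzyme of the urea cycle, rose by 1.94 ± 0.072, Slc25a13, the mitochondrial aspartate-glutamate carrier, by 1.73 ± 0.056, and Tdo2, which opens the tryptophan ring, by 2.29 ± 0.093. In gluconeogenesis and glycogen metabolism, 9 of 21 genes rose and 1, Pgm2, fell (13 and 2 when adjusted over the list alone; camera adjusted p = 1.86e-05). Slc37a4, the glucose-6-phosphate transporter, rose by 0.83 ± 0.059, Ppp1r3b, a glycogen-targeting phosphatase subunit, by 0.80 ± 0.060, and Ugp2, which makes UDP-glucose, by 0.79 ± 0.073. Known glucocorticoid targets rose in 11 of 19 cases and fell in 2, Lcn2 and Cdkn1a (12 and 3 when adjusted over the list alone; camera adjusted p = 0.000134). Among them Igfbp1 rose by 1.47 ± 0.088 and Zbtb16 by 0.57 ± 0.062, while Lcn2 stood at -0.64 ± 0.062.

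Detoxification and bile acid genes were higher in the knockout. Of 43 cytochrome P450 and other phase I genes, 27 rose and 3, Cyp51, Cyp2s1 and Adh7, fell (the same when adjusted over the list alone; median 0.51, or 0.39 with the mean of a gene's probe sets and 0.83 without the dimmest 50% of probe sets, camera adjusted p = 2.33e-10). Cyp4f14 rose by 2.52 ± 0.101, the carboxylesterase Ces2a by 2.20 ± 0.071, Cyp2d22 by 1.35 ± 0.078 and the aldehyde oxidase Aox1 by 1.28 ± 0.066. Among 48 conjugation enzymes and transporters 22 rose and 4 fell, namely Abcc4, Sult1c2, Abcg2 and Gsto1 (24 and 5 when adjusted over the list alone; camera adjusted p = 2.13e-06). Here Ugt2b34 rose by 1.77 ± 0.071, Sult1d1 by 0.95 ± 0.070 and Gsta4 by 0.74 ± 0.060. Bile acid synthesis and transport genes rose in 12 of 22 cases and none fell (12 and 0 when adjusted over the list alone; camera adjusted p = 3.04e-06). Besides Slc10a1, the steroid reductase Akr1d1 rose by 1.68 ± 0.10, the sterol carrier Scp2 by 1.08 ± 0.067, and the bile salt export pump Abcb11 by 1.60 ± 0.133.

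Genes of mitochondrial fatty acid oxidation and, as a list, peroxisomal genes were higher. Of 30 mitochondrial fatty acid oxidation genes, 21 rose and none fell (22 and 1 when adjusted over the list alone; median 0.32, camera adjusted p = 2.06e-09). Acaa2, the thiolase of the last step of the spiral, rose by 0.99 ± 0.052, and the dehydrogenases Acad11 and Acadm by 0.85 ± 0.057 and 0.67 ± 0.059 (Acadm by 0.43 after subtracting the median change of neighbouring genes). The carnitine carrier Slc25a20 rose by 0.62 ± 0.055, while Cpt1a, which controls entry of fatty acids, stood at 0.08 ± 0.052 and did not pass (adjusted p = 0.368). Of 53 peroxisomal genes, 26 rose and 5 fell, the latter being Vwa8 itself, Far1, Pex7, Abcd4 and Agps (31 and 6 when adjusted over the list alone; camera adjusted p = 9.99e-08). Vwa8 was on this list as fixed before the data were examined, and its fall is that of the deleted gene. Hao1, the hydroxyacid oxidase, rose by 1.73 ± 0.074 and Idh1, the cytosolic and peroxisomal isocitrate dehydrogenase, by 1.04 ± 0.048. Far1, a reductase needed for ether lipids, stood at -1.36 ± 0.058, and Far1 and Agps both act in ether lipid synthesis. Lipoprotein and lipid droplet genes rose in 17 of 34 cases and fell in 2, Fabp5 and Plin2 (18 and 4 when adjusted over the list alone; camera adjusted p = 8.52e-06). Mttp, which loads lipid onto apolipoprotein B, rose by 1.39 ± 0.076, Abca1 by 1.28 ± 0.073, Fabp1 by 1.27 ± 0.082 and Vldlr by 1.04 ± 0.054.

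Lists of respiratory chain, mitochondrial ribosome, citric acid cycle and ketone body genes passed camera at its preset correlation and missed with an estimated one. Of 37 complex I genes, 14 rose and none fell (19 and 0 when adjusted over the list alone; median 0.19, camera adjusted p = 8.54e-07; adjusted p = 0.0599 with an estimated correlation). For complexes II to V it was 10 of 48 with none lower (median 0.07, or 0.11 without wild-type replicate 1, camera adjusted p = 0.00289; adjusted p = 0.312 with an estimated correlation). Mitochondrial ribosome genes rose in 11 of 71 cases and fell in 2, Mrps16 and Mrpl54 (median 0.10; adjusted p = 0.00671, or 0.171 as the adjusted p with an estimated correlation). Citric acid cycle genes rose in 8 of 26 cases and fell in 3, Cs, Mdh2 and Idh2 (adjusted p = 0.0202, and adjusted p = 0.159 with an estimated correlation). Ketone body genes rose in 5 of 6 cases (adjusted p = 0.00289, and adjusted p = 0.0566 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial biogenesis, stood at 0.09 ± 0.071 and did not pass (adjusted p = 0.456). Mitochondrial dynamics and biogenesis genes (12 of 35 higher, 4 lower, camera adjusted p = 0.223) and mitochondrial import and proteostasis genes (8 of 41 higher, 4 lower, camera adjusted p = 0.737) did not pass as lists.

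Genes of the endoplasmic reticulum and its unfolded protein response were higher. Of 31 such genes, 22 rose and none fell (26 and 0 when adjusted over the list alone; median 0.39, camera adjusted p = 1.52e-13). Hspa5, the main chaperone there, rose by 0.69 ± 0.061, Hyou1 by 0.68 ± 0.055, Herpud1 by 0.58 ± 0.055 and the disulfide oxidase Ero1b by 1.14 ± 0.085. Targets of ATF4 in the integrated stress response went both ways, 16 of 44 higher and 7 lower (camera adjusted p = 0.0202; adjusted p = 0.239 with an estimated correlation). Antioxidant genes also went both ways. Of 29 NRF2 targets, 11 rose and 5 fell (camera adjusted p = 0.192), and of 31 other genes of peroxide and superoxide removal 10 rose and 4 fell (camera adjusted p = 0.0575). Cat, which encodes catalase, rose by 0.32 ± 0.055 and Sod2, the mitochondrial superoxide dismutase, by 0.32 ± 0.058, while Hmox1, the inducible heme oxygenase, stood at -0.44 ± 0.062 (adjusted p = 0.00113). Nqo1 was dim in both groups and did not pass, at -0.03 ± 0.115 (adjusted p = 0.883). Subtracting the median change of neighbouring genes left Cat at 0.13 (adjusted p = 0.139; 7.44e-07 to 0.139 over all alternatives).

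**Figure D2:**
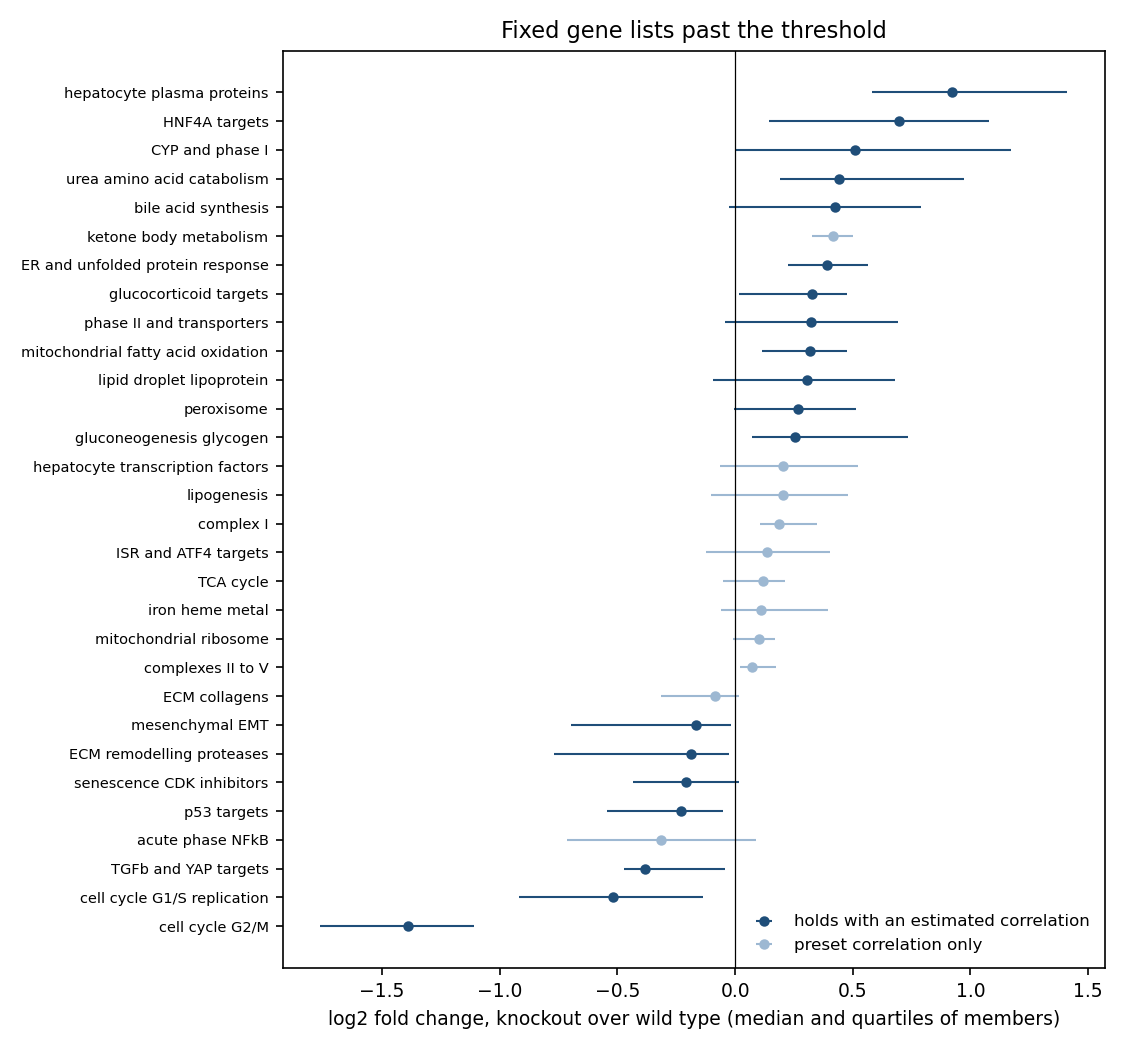
Median log2 fold change (horizontal axis, knockout over wild type) of the members of each of the 30 fixed gene lists that passed camera with its preset correlation; whiskers run from the lower to the upper quartile of members. Dark points are the 19 lists that also passed with an estimated correlation, and the list of G2/M genes lies furthest below 0, at -1.39.

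Of the 53 lists, genes of mitosis had the lowest median, and replication genes fell with them. Of 42 genes of the G2/M phases, 40 fell and 1, Smc4, rose (the same when adjusted over the list alone; median -1.39, camera adjusted p = 1.47e-35). With the correlation estimated for this list, 0.138, the camera adjusted p was 0.00926. Mki67, the proliferation marker, stood at -2.66 ± 0.115, the mitotic kinase Plk1 at -2.23 ± 0.076, the topoisomerase Top2a at -2.02 ± 0.058, the kinesin Kif23 at -2.06 ± 0.065, and Anln, which acts in cytokinesis, at -2.27 ± 0.081. Of 40 genes of G1/S and DNA replication, 26 fell and 2, Tk1 and E2f1, rose (29 and 2 when adjusted over the list alone; median -0.52, camera adjusted p = 5.62e-14). Ccnd1, which encodes cyclin D1, stood at -0.96 ± 0.051, Mcm4 of the replicative helicase at -1.08 ± 0.056, Rrm1 at -0.91 ± 0.054 and Uhrf1 at -1.40 ± 0.081. Targets of p53 fell in 14 of 25 cases and none rose (the same when adjusted over the list alone; median -0.23, camera adjusted p = 8.36e-06). Eda2r stood at -0.91 ± 0.076, Tnfrsf10b at -0.82 ± 0.088, Perp at -0.62 ± 0.057 and Mdm2 at -0.55 ± 0.062. Perp and Mdm2 lie on chromosome 10, whose genes were shifted down as a group, and subtracting the median change of neighbouring genes left Perp at -0.42 and Mdm2 at -0.31, both past the threshold. The list of senescence genes and cell cycle inhibitors fell in 9 of 21 cases and rose in 1 (10 and 2 when adjusted over the list alone; camera adjusted p = 0.00289), and the members with the smallest p that fell, Ccl2, Ccl7 at -1.99 ± 0.144 and Cxcl1 at -1.82 ± 0.156, are secreted chemokines. The member that rose in the adjustment over all genes was Rbl2, a relative of the retinoblastoma protein, at 0.65 ± 0.052.

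Targets of TGF-beta and YAP, mesenchymal genes and genes of matrix remodelling were lower. Of 23 TGF-beta and YAP targets, 14 fell and none rose (14 and 1 when adjusted over the list alone; median -0.38, camera adjusted p = 4.83e-06). Ankrd1 stood at -1.79 ± 0.074, Ccn1, a matricellular protein, at -1.51 ± 0.080, Ajuba at -1.12 ± 0.073 and the receptor kinase Axl at -0.64 ± 0.067. Mesenchymal genes fell in 15 of 34 cases and rose in 2, Fn1 and Cdh11 (the same when adjusted over the list alone; camera adjusted p = 2.95e-06), with the actin-binding Cnn2 at -1.74 ± 0.084, Tgfb3 at -1.19 ± 0.062 and the hyaluronan receptor Cd44 at -1.07 ± 0.072. Matrix proteases and their inhibitors fell in 13 of 30 cases and rose in 1, Mmp19 (14 and 1 when adjusted over the list alone; camera adjusted p = 1.27e-05). Among these Adamts9 stood at -1.41 ± 0.086, Adam12 at -1.12 ± 0.094, Plaur, the urokinase receptor, at -1.06 ± 0.077, and Adamts1 at -0.98 ± 0.065. Collagens and other matrix genes fell in 13 of 45 cases and rose in 3, Postn, Fn1 and Lamc1 (camera adjusted p = 0.00531; adjusted p = 0.0566 with an estimated correlation). Acute phase and NF-kB genes fell in 15 of 33 cases and rose in 7 (camera adjusted p = 0.0202; adjusted p = 0.156 with an estimated correlation).

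Markers of other liver cell types changed in both directions. Of 21 stellate cell and fibroblast markers, Postn rose by 2.67 ± 0.072 while Fbln2 (-1.26 ± 0.076) and Timp1 (-0.62 ± 0.086) fell. Of 18 endothelial markers Flt1 rose (0.85 ± 0.085), and of 19 macrophage and leukocyte markers Cd14 fell (-0.45 ± 0.059). Of 15 cholangiocyte and progenitor markers 1, Krt23, rose and 5, Cftr, Cd24a, Tnfrsf12a, Krt7 and Aqp1, fell. None of these 4 lists passed camera, with adjusted p of 0.737, 0.701, 0.639 and 0.144. Of 13 reference genes often used for normalization, 3 fell, Gusb (-0.92 ± 0.059), Actb (-0.68 ± 0.075) and Polr2a (-0.23 ± 0.057), and none rose (camera adjusted p = 0.0748). These members were named after their values were seen. Genes of glycolysis (7 of 28 higher, 3 lower), cholesterol synthesis (5 of 21 higher, 5 lower), the interferon response (2 of 37 higher, 5 lower) and Wnt targets (2 of 24 higher, 2 lower) did not pass as lists either, with camera adjusted p of 0.0554, 0.722, 0.443 and 0.479.

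Lipogenesis genes rose in 15 of 32 cases and fell in 4, Fads3, Me1, Agpat3 and Pparg (camera adjusted p = 0.00244; adjusted p = 0.0882 with an estimated correlation). Iron and heme genes rose in 10 of 24 cases and fell in 2, Hmox1 and Slc40a1 (camera adjusted p = 0.0334; adjusted p = 0.0882 with an estimated correlation and 0.0623 without knockout replicate 2; 4.40e-05 to 0.0882 over all alternatives). In all, 30 of the 53 lists passed camera at its preset correlation, 21 higher and 9 lower in the knockout, and 19 of them (12 higher and 7 lower) also passed with an estimated correlation. Every list described here without a second p is among those 19 or did not pass camera with either correlation. Fry passed 45 of the 53 lists, among them lists that camera did not pass, such as glycolysis (fry adjusted p = 8.79e-05). In each of the 19 the camera adjusted p was larger with an estimated correlation than with the preset one. With an estimated correlation it ran from 0.00142 for amino acid breakdown and urea synthesis to 0.0385 for p53 targets. It was larger also where the estimated correlation lay below 0.01, as for bile acid genes (-0.031) and amino acid breakdown (-0.0088). A higher correlation between members is therefore not what made p larger in those lists.

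Genes on several chromosomes were shifted as a group. With gene positions from assembly GRCm38.p6, chromosome 3 had 267 genes higher and 63 lower, and the median log2 fold change of its brighter genes (those above the median signal of all genes) was 0.21. Chromosome 1 had 288 genes higher and 89 lower (median of brighter genes 0.17) and chromosome 2 had 325 higher and 83 lower (0.16). Chromosome 10 had 50 genes higher and 242 lower (-0.18), and chromosome 5 had 63 higher and 236 lower (-0.14). In camera with an estimated correlation, adjusted p was 0.0184 for chromosome 1, 0.00871 for chromosome 2, 0.0166 for chromosome 3, 0.0121 for chromosome 5 and 0.00975 for chromosome 10. Chromosome 7, with 112 higher and 227 lower (-0.08), passed narrowly at 0.0494, missed with the preset correlation at an adjusted p of 0.235, and passed in 2 of the 9 alternatives run (without knockout replicate 3 or 4), with adjusted p from 0.0241 to 0.126. Of the genes named by the rule fixed beforehand, 34 that passed the threshold lie on these 6 chromosomes, and 28 of them moved with their chromosome and 6 against it. By the counts above, most of all genes that passed on these chromosomes also moved with them, so this is no trait of the named genes. Over all alternatives the rises of Idh1 and Aox1 on chromosome 1 were as small as 0.75 and 0.96. That of Hspa5 on chromosome 2 was as small as 0.50, and each of these genes passed throughout.

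**Figure D3:**
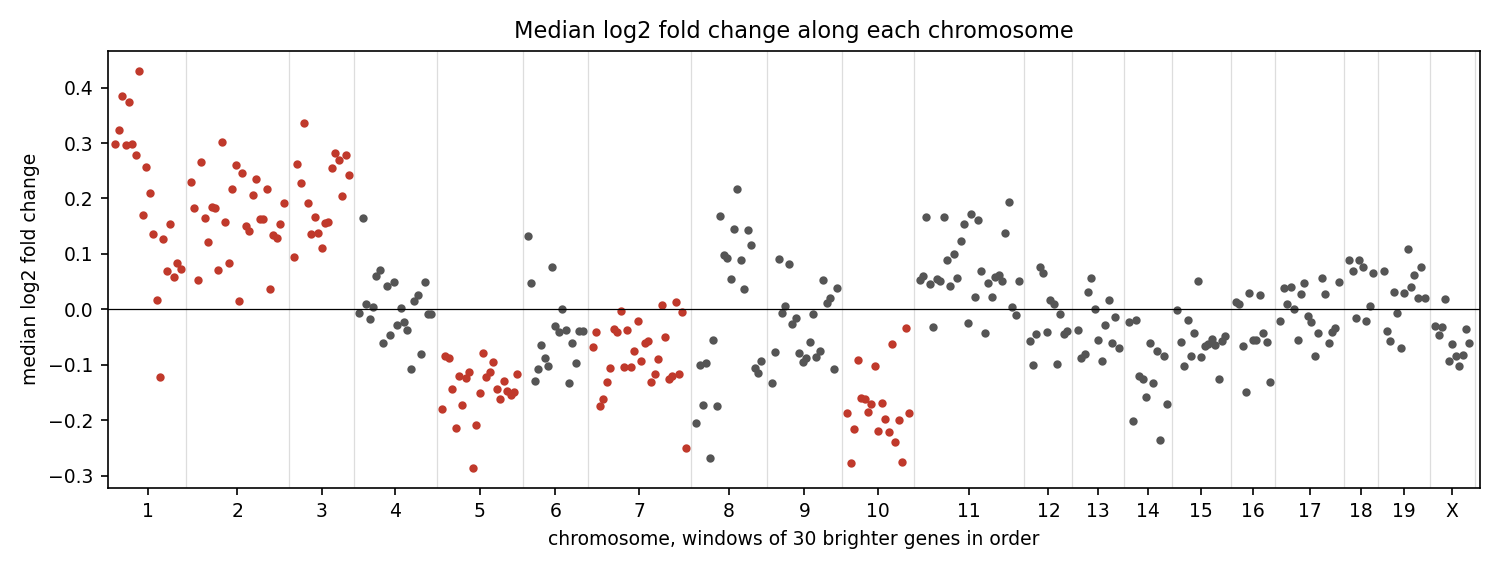
Median log2 fold change (vertical axis, knockout over wild type) in consecutive windows of 30 brighter genes along each chromosome (horizontal axis, in order of position); red marks the 6 chromosomes that passed the test of a shift. All 17 windows of chromosome 3 and all 28 of chromosome 2 lie above 0, and all 23 of chromosome 5 and all 19 of chromosome 10 lie below it.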

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

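The window test along the chromosomes and the test of plasma protein genes at like signal levels were chosen after the results were seen. In 7 of the 184 groups of 4 arrays examined for named genes (3.8%), 1 array lay further from the rest than Dixon's critical value at 95% allows, where chance gives about 1 in 20. Knockout replicate 1 read low for Igfbp1 (6.97, the others 7.21 to 7.24) and for Cyp4f14 (6.05, the others 6.37 to 6.39). Knockout replicate 2 read high for Sod2 (9.76, the others 9.67 to 9.68) and for Ces2a (8.42, the others 8.34 to 8.35). Knockout replicate 3 read high for Mki67 (6.48, the others 6.05 to 6.12). Wild-type replicate 3 read low for Idh1 (10.08, the others at 10.1), and wild-type replicate 4 read low for Zbtb16 (8.84, the others 9.0 to 9.01). All 7 genes passed the threshold with every array left out in turn.

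The real grouping gave far more changes than any other. Of the 35 ways to split the 8 arrays into 4 and 4, only 1, the real one, gave as many changed probe sets (4585), changed genes (4626) or genes changed at least 2-fold (450), and the highest count in the others was 0 for each in limma. At an unadjusted p under 0.05 the real grouping gave 6902 genes and the highest of the others 1281. In the other groupings the genotype difference adds to the spread within each side, so their counts are low for that reason too. Chance in the grouping is argued against as the source of these counts, at a share of 1 in 35. That is the smallest share these splits can give, so chance is not excluded.

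The fall of G2/M genes is the first of 3 patterns weighed. A shift of a few chromosomes is argued against by its size. The medians of brighter genes ran from -0.18 on chromosome 10 to 0.21 on chromosome 3, against -1.39 for the list. The members that changed lie on 16 chromosomes. Subtracting the median of the other brighter genes of each member's chromosome left 106% of the list's median, -1.47. With chromosome medians so small this subtraction could not have removed the pattern, so it adds nothing to the comparison of sizes. An overall scaling of the arrays is argued against by the array medians, all between 4.27 and 4.33, and by the median change over all genes, -0.003. With these so alike the reference genes could hardly have shown a scaling. Their median, at 6.83% of the list's, therefore adds little. Loss of VWA8, a difference in growth state or density of the cultures at harvest, and a slower dividing clone stay open, and none of them was tested.

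The rise of plasma protein genes is the second. Chromosome shifts are argued against by their size, since no chromosome's brighter genes had a median above 0.21, against 0.92 for the list. Subtracting chromosome medians left 101% of the list's median, but so small a correction could not have removed the rise. A common scaling of the arrays is argued against by the median change over all genes, -0.003. The reference genes' median, at -10.3% of the list's, adds little to that. Loss of cells of another type from the knockout cultures would raise all these genes by 1 factor, if the lost cells expressed none of them. The 15 members with a wild-type mean from 8 to 11 ran from -0.40 for Ambp to 1.79 for Vtn. This range argues against such a loss as the cause of the whole rise, for these 15 members. Of them, 80% lay more than 3 SE from the median of the whole list. The SE covers the spread between arrays and not differences between probe sets, so that share alone decides little. Whether such a loss adds to the rise cannot be told apart, since 20% of the 10 markers of other cell types that were bright in wild-type cells and changed had risen, and 8 had fallen, in a line that may itself express some of them. With those left open, a more differentiated hepatocyte state of the knockout cultures is a hypothesis, and whether it follows from the loss of VWA8 or from the choice of a clone was not tested.

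The shift of whole chromosomes is the third. A few strongly regulated genes could hardly move medians taken over so many genes. That 96.1% of the summed medians was left without genes on a fixed list or changed at least 2-fold therefore decides little. The counts show that many genes moved, such as 267 higher and 63 lower on chromosome 3 and 50 higher and 242 lower on chromosome 10. Gene length and signal level are argued against, since 102% was left after subtracting the medians of their deciles. A difference in chromosome copy number between the wild-type and knockout populations stays open. The median went the way of the chromosome in 97.8% of the 135 windows of 30 brighter genes on the 6 chromosomes, but 200 shuffled gene orders within each chromosome gave 97.0% to 100%, so this share follows from the shift itself and decides nothing. DNA was not analysed here, so copy number cannot be told apart from other causes that act on many genes of a chromosome, and GC content was not tested.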

How the results depend on the processing

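The subtraction of local chromosome medians was chosen after seeing the data; all other alternatives were fixed beforehand. Over the alternatives, the count of changed genes ran from 3717 to 5573 and that of genes changed at least 2-fold from 414 to 468. Leaving out 1 array gave 3333 to 3740 changed probe sets, 3858 to 4038 genes, 443 to 468 genes at least 2-fold, 30 to 32 lists, 5 or 6 chromosomes, and a Vwa8 log2 fold change from -3.82 to -3.73. With the replicate block 2849 probe sets passed (4585 without it). In place of the 30 lists, camera with an estimated correlation passed 19 and fry, which does not compare a list with other genes, passed 45. The causes of these differences were not tested. What arrays of the same replicate number share is not given in the labels. Such arrays correlated weakly in their deviations, by 0.055, 0.028, 0.078 and 0.030, yet 6 of the 8 arrays correlated best with their own number. The second principal component ranked replicates 2, 4, 1 and 3 in that order in both genotypes. It ran from 25.1 to -47.0 in wild-type arrays and from 11.4 to -18.8 in knockout arrays. A batch or pairing shared by number therefore stays possible, and the main fit ignores it. With the block 3717 genes, 450 genes at least 2-fold and 29 lists passed.

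No list that passed turned its direction under any alternative, and the share of higher genes among changed genes moved by under 10 percentage points (to 55.4% with median centring). Subtracting local chromosome medians gave 4428 changed genes, of which 3374 were among the 4626 with the same direction, 1053 were new, and 1, Trak2, named after its values were seen, turned from 0.19 ± 0.054 to -0.18 ± 0.054. The other 1251 of the 4626 no longer passed. The subtraction ended the calls of Cat and Ttr, and brought in Ppargc1a at 0.24 (adjusted p = 0.0460; 0.0460 to 0.734 over all alternatives). Nqo1, never past the threshold, ran from -0.11 to 0.039 when 1 array was left out and was above 0 without wild-type replicate 2 (0.016) or knockout replicate 3 (0.039). The list of iron and heme genes lost its call in 6 of 19 alternatives. No background signal was used, so the level below which the arrays show nothing was not measured.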

Other observations

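Gene families defined by the shared stem of their symbols, a search made after the data were seen, pointed to some members outside the fixed lists. Of 21 aldehyde dehydrogenase genes, 15 rose and none fell (median 0.28), with Aldh8a1 at 1.95 ± 0.104 and Aldh7a1 at 1.14 ± 0.061. Of 28 genes with the stem Sec, some of them coat or translocon components of the secretory pathway, 12 rose and 1 fell, with Sec24d at 1.73 ± 0.073. Of 16 genes of the ABCA transporters 6 rose and none fell, among them Abca6 at 1.61 ± 0.085 and Abca8b at 1.51 ± 0.066. In the other direction, 8 of 17 genes of the PTPN tyrosine phosphatases fell and none rose, with Ptpn13 at -1.01 ± 0.096, and 7 of 13 CXCL chemokine genes fell and 1, Cxcl17, rose, with Cxcl16 at -1.23 ± 0.096. Of 9 genes of the COP9 signalosome 5 rose and none fell, with Cops7b at 0.44 ± 0.061. Of 340 families tested with camera at its preset correlation, 10 were higher and 6 lower, and with an estimated correlation 0 passed (26 had an unadjusted p under 0.05); for the aldehyde dehydrogenases, p was 0.000806 before adjustment and adjusted p = 0.274.

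Chromosome 8 did not pass the test of a shift, with an adjusted p of 0.652 and a median of -0.02 among its brighter genes, yet its windows of 30 brighter genes fell into runs. The first 7 had medians from -0.27 to -0.05, the next 10 from 0.04 to 0.22, and the last 3 from -0.11 to -0.09. All 12 windows of chromosome 14, which carries Vwa8, lay below 0. The chromosome had an adjusted p of 0.0730 and passed in 1 of the 9 alternatives run, the one without the dimmest 50% of probe sets, with adjusted p from 0.0257 to 0.130. On chromosome 1, which passed, the first 11 windows had medians from 0.17 to 0.43 and the 9 later ones from -0.12 to 0.15, with the break chosen from these values.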
